A study of Homo sapiens with 12 samples.

How the data were processed

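The series holds 12 Affymetrix U133 Plus 2.0 arrays of total RNA from the lymphoma lines OCI-Ly7 and Pfeiffer, 48 h after transfection with BCL6 or control siRNA, 3 arrays per group. The deposited table gives log2 values for 54675 probe sets. Per the submitters' processing notes these came from MAS5, with affy, and no version is given. Transformed back, each array's mean after trimming 2% at either end was 500.0, so the deposited log2 signals had been scaled to one level per array by the authors and were not normalized further here. No detection calls were used here. The median signal was 71.4 to 85 on the linear scale, and 21.2% to 23.1% of probe sets read below 16. MAS5 subtracts mismatch signals, which makes dim probe sets noisy. The median, the share of dim probe sets and the 3' to 5' ratios of GAPDH and ACTB did not separate siRNA from control arrays in either line (exact two-sided permutation p = 0.2 to 0.8). With 3 arrays against 3 this test cannot go below 0.1, so it shows only that the groups overlapped. Pfeiffer siRNA replicate 3 stood apart, with log2 ratios of -0.027 for GAPDH and 0.388 for ACTB, against -0.134 to -0.094 and 0.278 to 0.308 on the other Pfeiffer arrays. Arrays of a group correlated at 0.986 to 0.991 and arrays of different lines at 0.653 to 0.671, and no 2 arrays held identical values. No batch or scan date was given in the labels, so none was tested.

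Probe sets were named from the platform annotation of 2016: 41091 carried 1 gene symbol, 1801 several and 11721 none, and 62 were controls. Only those with 1 symbol were used. A RefSeq gene table (GRCh38.p14) held the gene identifiers of 41037 of these and changed 0 symbols, and its coordinates were not used. Of the genes to be named in every case, 3 were not analysed here, and neither was 1 B cell marker.

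Linear signals were turned into log2(signal + 16), which understates the change of dim genes. Each of 19775 genes was represented by the probe set with the highest mean over all arrays. The upper 0.5 of genes was tested, by the higher of the means of the lines, which left 9888 genes with a lowest level of 7.91 (a signal of 223.9). A gene bright in one line could therefore be dim in the other. The p-values come from limma (lmFit and eBayes with a trend), fitted on all 12 arrays with 4 group means, which gave 8 residual degrees of freedom and a median of 6.7 prior ones. Contrasts were BCL6 siRNA minus control in each line, their average, and Pfeiffer minus OCI-Ly7. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes, with 0.05 as the threshold. SE is limma's moderated standard error.

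The groups, the tests, 19 pathway lists, 5 lists of cell type markers and the alternatives were fixed before the data were examined. Lists with at least 5 tested genes, 20 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, beside camera with an estimated correlation and fry. With an estimated correlation 5 of 8 lists kept their call in OCI-Ly7, 8 of 11 in Pfeiffer, 1 of 8 on average and 4 of 8 for the difference. Lists share members: CD69 and PRDM1, for example, each stand in 2 of them. The genes named are the 12 largest rises and 12 largest falls per line among called genes with no overlap of siRNA and control arrays, the 8 largest rises and 8 largest falls in both lines, the 6 most positive and 6 most negative differences, up to 4 genes of a list with the lowest p, and a fixed set of genes linked to BCL6. Alternatives were quantile normalization, pseudocounts of 1 and 64, other filters on dim genes, other ways to treat several probe sets of a gene, limma without a trend, with array weights, with a replicate block or per line, a 2-fold minimum, and each array left out in turn.

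The tests were also tried on 10 simulated data sets built from the means and spreads of these 9888 genes, with 200 genes changed per line. For OCI-Ly7 50%, 75.8% and 90.9% of genes changed by 0.4, 0.7 and 1 on the log2 scale were recovered, and 4.56% of calls were false. For Pfeiffer the shares were 51.5%, 76.4% and 92.6%, with 5.05% false. A G2/M list shifted by 0.2 in Pfeiffer was called in 10 of 10 data sets, and 0% of the unshifted lists were. The simulated genes varied independently of each other, whereas the correlation estimated for the real G2/M list was 0.194. The share of false list calls in the simulation therefore does not carry over to these arrays. Errors were drawn as normal, with limma's own estimate of each gene's spread, the same in both lines. The shares for genes thus hold where the assumptions of the test are met. They also rest on 200 changed genes per line, against 1603 called in Pfeiffer. R 4.3.3, limma 3.58.1, the package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.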

Results

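Total RNA from 2 human diffuse large B-cell lymphoma lines, OCI-Ly7 and Pfeiffer, was measured on 12 Affymetrix U133 Plus 2.0 arrays. Both lines are of the germinal centre B-cell type, in which BCL6, a transcriptional repressor of germinal centre B cells, is highly expressed. The cells had been transfected with an siRNA against BCL6 or with a non-target control siRNA, and RNA was taken after 48 h. Each line had 3 control and 3 BCL6 siRNA arrays. The titles of the Pfeiffer controls say shRNA where their descriptions and the design text say siRNA, so the kind of control oligonucleotide in that line is open. The comparisons ask which transcripts changed after BCL6 siRNA in each line, what the lines had in common and where they differed. The labels give no siRNA sequence, so effects of the siRNA on transcripts other than BCL6 could not be looked at. Array signals carry no read depth, and the number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. All changes are given as log2(signal + 16) of BCL6 siRNA minus control.

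BCL6, the targeted gene, fell in both lines, and further in Pfeiffer. In OCI-Ly7 the brightest of 3 BCL6 probe sets read 13.50, 13.57 and 13.59 on the control arrays and 13.13, 13.10 and 13.15 on the siRNA arrays. The means were 13.55 ± 0.05 and 13.13 ± 0.02 (SD, n = 3 each). The change of -0.42 ± 0.08 (SE) left 74.6% of the BCL6 signal, with a 95% confidence interval of 66.7% to 83.3% (limma, adjusted p = 0.00731). In Pfeiffer the same probe set read 13.86, 13.92 and 14.01 on the control arrays and 13.11, 13.04 and 12.75 on the siRNA arrays, with means of 13.93 ± 0.08 and 12.97 ± 0.19 (SD, n = 3 each). The change of -0.96 ± 0.08 (SE) left 51.3%, with an interval of 45.9% to 57.3% (limma, adjusted p = 5.31e-07). The fall was deeper in Pfeiffer, with a difference of -0.54 (limma, adjusted p = 0.00496). The second probe set left 71.3% in OCI-Ly7 and 40.9% in Pfeiffer. The third left 51% in Pfeiffer but 89.2% in OCI-Ly7, where its change of -0.17 missed the threshold (limma, adjusted p = 0.464 over probe sets). For each probe set and line the exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow.

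**Figure D1:**
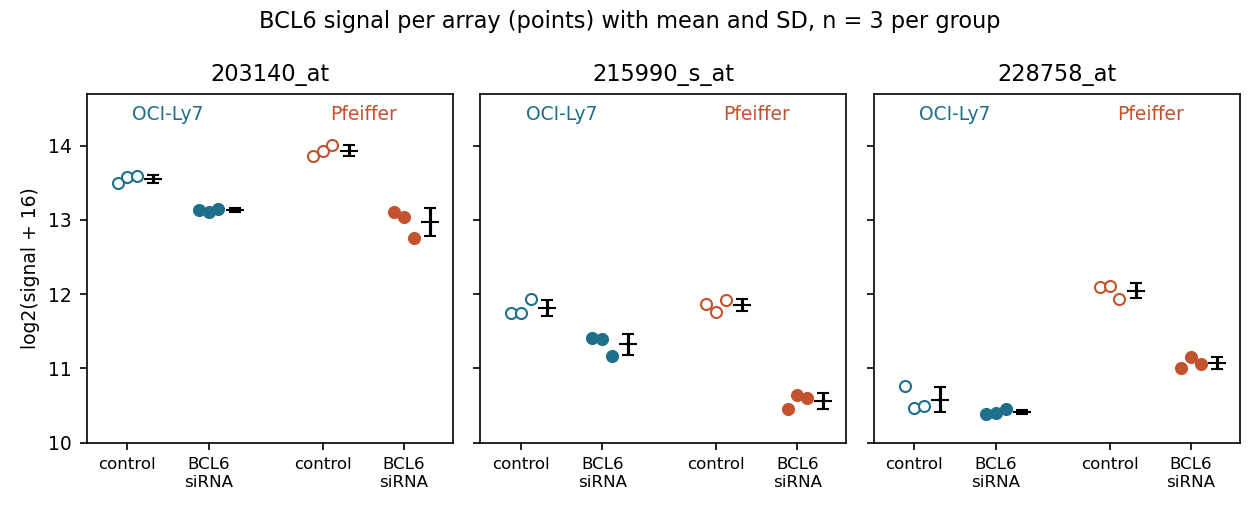
BCL6 signal, as log2(signal + 16), on each array for the 3 BCL6 probe sets, with open points for control arrays, filled points for BCL6 siRNA arrays, and the mean with SD beside them (n = 3 per group). The siRNA arrays lie below the controls for every probe set in both lines, by the least for the third in OCI-Ly7 (-0.17) and by the most for the second in Pfeiffer (-1.29).

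In OCI-Ly7, the largest rises that held on leaving out any array were those of SLC25A30, a mitochondrial carrier (1.66 ± 0.17 SE, adjusted p = 0.000109), LIMD1, a LIM domain scaffold protein (1.37 ± 0.16, adjusted p = 0.000252), PRSS2, a trypsinogen (1.20 ± 0.17, adjusted p = 0.000977), and HSP90B1, a chaperone of the endoplasmic reticulum (1.10 ± 0.07, adjusted p = 4.1e-07). The largest such falls were those of APOOL, a mitochondrial inner membrane protein (-1.67 ± 0.22, adjusted p = 0.000639), FADS2, a fatty acid desaturase (-1.41 ± 0.23, adjusted p = 0.00388), NETO2 (-1.11 ± 0.19, adjusted p = 0.00542) and the antisense RNA FAM167A-AS1 (-0.87 ± 0.07, adjusted p = 2.9e-06). CD69, an early activation antigen that BCL6 is known to repress, rose by 1.32 ± 0.30 (adjusted p = 0.0304), but its call ended without any of the 6 OCI-Ly7 arrays, with adjusted p up to 0.115. The 7 others of the 12 largest rises were WNT7B (1.82), SHROOM1 (1.60), TYMP (1.48), RNASE6 (1.47), CA6 (1.26), PRKAR1B (1.23) and GZMB (1.11). The 8 others of the 12 largest falls were LPAR2 (-1.73), LONRF3 (-1.34), FBLN1 (-1.18), RPS6KA6 (-1.17), CEBPD (-1.11), MYH11 (-0.98), RAB20 (-0.93) and TMEM145 (-0.89). For these 24 genes, all siRNA arrays of the line lay on one side of all its control arrays.

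Each of those 15 others lost its call without some array, with adjusted p up to 0.154 for WNT7B and 0.152 for LONRF3. Every OCI-Ly7 array ended several of these calls when left out. Without probe sets that can bind related transcripts, WNT7B stood at -0.21 and LIMD1 at 0.50 (adjusted p = 0.181). Among the probe sets with 1 gene symbol that passed the filter, PRSS2 and HSP90B1 have only such ones, so that check could not be made for them. Their second probe sets gave 0.79 and 0.60. With the mean of all probe sets of a gene, APOOL stood at -0.56 (adjusted p = 0.221), FADS2 at -0.36 (adjusted p = 0.651) and LIMD1 at 0.48 (adjusted p = 0.24). With the line fitted on its own 6 arrays APOOL (adjusted p = 0.0529) and NETO2 (adjusted p = 0.15) were not called.

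Among the gene lists fixed beforehand, cholesterol synthesis rose in OCI-Ly7 (mean 0.21 over 15 genes, camera adjusted p = 1.08e-07). Of its members 6 rose and none fell, or 10 and 0 when adjusted over the list alone. Among these, DHCR7, MSMO1 and SQLE each lost the call without any of 4 arrays, and LSS passed narrowly (limma, adjusted p = 0.0495). The isomerase IDI1 rose by 0.39 (adjusted p = 0.00405). It stood at 0.09 without probe sets that can bind related transcripts (adjusted p = 0.798) and was not called with the mean of its probe sets either (0.18, adjusted p = 0.278). The MHC class II presentation genes rose as a list (mean 0.18 over 18 genes, camera adjusted p = 5.48e-06). It had 3 members higher and 0 lower, or 9 and 0 when adjusted over the list alone. The class II beta chain HLA-DRB1 rose by 0.38 ± 0.06 (adjusted p = 0.00231). The B cell markers rose (mean 0.20 over 8 genes, camera adjusted p = 0.000698). Of these 2 rose and 0 fell, or 3 and 0 when adjusted over the list alone. They included CD79B, a signalling chain of the B cell receptor (0.38 ± 0.04, adjusted p = 0.000252), which kept its size but not its call with the mean of its probe sets (0.38, adjusted p = 0.333). The B cell activation and exit genes rose (mean 0.24 over 18 genes, camera adjusted p = 1.9e-05; adjusted p = 0.0688 with an estimated correlation). Of these 4 rose and 0 fell, or 5 and 0 when adjusted over the list alone, among them the activation marker CD83 (0.45 ± 0.05, adjusted p = 0.000399).

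Known BCL6 repression targets rose in OCI-Ly7 as a list (mean 0.20 over 21 genes, camera adjusted p = 0.000467). Of its members 5 rose and 1 fell, or 7 and 1 when adjusted over the list alone. The 1 that fell, NFKB1, was also the 1 called lower in Pfeiffer and on average. Its call in OCI-Ly7 was lost without any of 9 arrays. LITAF, an endosomal membrane protein, rose by 0.55 ± 0.07 (adjusted p = 0.000876), and SUB1, a transcriptional coactivator, by 0.46 ± 0.07 (adjusted p = 0.00279). PRDM1, which encodes the plasma cell regulator BLIMP1, rose by 0.47 ± 0.11 (adjusted p = 0.0294), a call lost without control replicate 1, siRNA replicate 2 or siRNA replicate 3 of OCI-Ly7 (adjusted p up to 0.0993). LITAF lost its call with the mean of its probe sets, dim ones included (0.44, adjusted p = 0.234), while its second probe set gave 0.52, and SUB1 without probe sets that can bind related transcripts (adjusted p = 0.0583).

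The plasma cell and secretory genes were called higher in OCI-Ly7 (mean 0.12 over 24 genes, camera adjusted p = 0.0114; adjusted p = 0.353 with an estimated correlation). Of these 5 rose and 0 fell, or 7 and 1 when adjusted over the list alone. HSP90B1 led, followed by TNFRSF17, the BCMA receptor of plasma cells (0.78 ± 0.08, adjusted p = 7.76e-05), and XBP1, a regulator of secretion (0.50 ± 0.05, adjusted p = 0.000151). The mean of all XBP1 probe sets turned to -0.06, and the list was not called without OCI-Ly7 control replicate 2 (adjusted p = 0.154) or with the line fitted on its own arrays (adjusted p = 0.0763). The B cell receptor signalling list was called higher (mean 0.08 over 25 genes, camera adjusted p = 0.03; adjusted p = 0.0948 with an estimated correlation), with 3 higher and 1 lower, or 6 and 1 when adjusted over the list alone. RASGRP3, a Ras exchange factor of this pathway, went the other way (-0.57 ± 0.10, adjusted p = 0.00839), a call lost with the mean of its probe sets (-0.09, adjusted p = 0.899) or with the line fitted on its own arrays (adjusted p = 0.077). The list's call ended without siRNA replicate 2, siRNA replicate 3 or control replicate 2 of OCI-Ly7 (adjusted p = 0.0893, 0.112 and 0.11). Quantile normalization (adjusted p = 0.0637) and other settings for probe sets and dim genes, up to an adjusted p of 0.127, ended it too. The interferon response list was called higher (mean 0.17 over 25 genes, camera adjusted p = 0.00866), although 0 members passed in limma, also when adjusted over the list alone. At an unadjusted p of 0.05, 5 were higher and 0 lower, and the antigen transporter TAP1 stood at 0.29 (adjusted p = 0.0699). The call was lost without a filter on dim genes (adjusted p = 0.0607) and with a stricter one (adjusted p = 0.0673).

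Across all 9888 genes tested in OCI-Ly7, 265 passed an adjusted p of 0.05 in limma, 167 higher and 98 lower, and 22 of them changed at least 2-fold. At an unadjusted p of 0.05, 1532 passed. The siRNA and control arrays did not overlap for 22.9% of genes, where chance gives 10%. In OCI-Ly7 the lists of G2/M genes (mean -0.01, camera adjusted p = 0.604), S phase genes (-0.02, adjusted p = 0.613), DNA damage genes (0.03, adjusted p = 0.967), stress response genes (0.02, adjusted p = 0.604) and germinal centre genes (-0.04, adjusted p = 0.368) were not called. Limma called 0 members of the G2/M, S phase and DNA damage lists, against 1, 3 and 2 at an unadjusted p of 0.05. The count over all genes fell to 101 without siRNA replicate 1, 135 without siRNA replicate 3, 149 without control replicate 3 and 159 without control replicate 1 of OCI-Ly7.

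In Pfeiffer, PRDM1 rose by 1.40 ± 0.11 (adjusted p = 3.94e-07), together with INSIG1, which holds sterol regulators in the endoplasmic reticulum (1.43 ± 0.08, adjusted p = 2.67e-08), CMAS, an enzyme that activates sialic acid (1.92 ± 0.13, adjusted p = 1.43e-07), and CSRP2, a LIM domain protein (1.92 ± 0.14, adjusted p = 2.32e-07). SPIB, an Ets transcription factor of B cells, fell by 1.66 ± 0.09 (adjusted p = 2e-08), as did the lymphoid nuclear factor AFF3 (-2.14 ± 0.12, adjusted p = 2.67e-08), ALOX5AP, needed for leukotriene synthesis (-1.55 ± 0.07, adjusted p = 2.85e-09), the ubiquitin ligase RNF144B (-1.52 ± 0.10, adjusted p = 9.63e-08) and NAPSB (-2.46 ± 0.15, adjusted p = 4e-08). The 8 others of the 12 largest rises were LINC01943 (2.23), C2CD4A (1.84), SOX2 (1.59), LILRA2 (1.55), IQGAP2 (1.54), RAB23 (1.53), ERV3-1 (1.47) and IL4I1 (1.41). The 7 others of the 12 largest falls were KLRA1P (-2.08), LINC01215 (-1.97), PALM2 (-1.74), MAP3K7CL (-1.69), GLI1 (-1.65), SATB1 (-1.57) and SCN4A (-1.56).

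Of these 24 genes 23 kept their call without each array in turn; IL4I1 lost it without any of the 6 Pfeiffer arrays (adjusted p up to 0.129). The LILRA2 probe sets disagreed, with 1 called in the other direction (-1.06), and the gene's change was -1.53 with a pseudocount of 1. The CMAS probe sets disagreed too, and the second stood at -0.06. With the mean of all probe sets LILRA2 (0.26, adjusted p = 0.388), IQGAP2 (0.71, adjusted p = 0.231) and SATB1 (-0.61, adjusted p = 0.0735) were not called, nor was SATB1 with the line fitted on its own arrays (adjusted p = 0.0511). With a pseudocount of 1 neither LINC01943 (adjusted p = 0.0853) nor C2CD4A (adjusted p = 0.134) was. SOX2, LILRA2, IQGAP2 and ERV3-1 were dim in Pfeiffer controls, with means of 5.89, 4.53, 4.25 and 4.87 against 7.91 for the lowest level kept in the brighter line.

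Cell cycle genes rose in Pfeiffer. In the G2/M list, 15 of 29 genes rose and 0 fell, or 19 and 0 when adjusted over the list alone (mean 0.26, camera adjusted p = 3.91e-11). The proliferation marker MKI67 rose by 0.54 ± 0.06 (adjusted p = 2.13e-05), the kinetochore motor CENPE by 0.48 ± 0.07 (adjusted p = 0.000326) and the kinetochore protein NDC80 by 0.36 ± 0.06 (adjusted p = 0.000755). In the S phase list, 13 of 28 rose and 0 fell, or 14 and 0 when adjusted over the list alone (mean 0.19, camera adjusted p = 3e-07; adjusted p = 0.0893 with an estimated correlation). They included RRM2 (0.56 ± 0.05, adjusted p = 3.24e-06) and RRM1 (0.34 ± 0.05, adjusted p = 0.000328), the subunits of ribonucleotide reductase. The DNA damage sensing and repair list was called higher (mean 0.09 over 22 genes, camera adjusted p = 0.0362; adjusted p = 0.27 with an estimated correlation). Of these 5 rose and 0 fell, or 6 and 1 when adjusted over the list alone. The helicase BLM rose by 0.54 ± 0.05 (adjusted p = 6.13e-06). That list was not called without siRNA replicate 1, control replicate 1 or control replicate 3 of Pfeiffer (adjusted p = 0.119, 0.0761 and 0.129), nor with the line fitted on its own arrays (adjusted p = 0.0597).

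Plasma cell and stress genes also rose in Pfeiffer. Of 24 plasma cell and secretory genes 8 rose and 1 fell, or 8 and 2 when adjusted over the list alone (mean 0.26, camera adjusted p = 0.000125; adjusted p = 0.0918 with an estimated correlation). Besides PRDM1 they included IRF4, a transcription factor of plasma cell differentiation (0.82 ± 0.10, adjusted p = 3.98e-05), and HSP90B1 (0.72 ± 0.07, adjusted p = 3.26e-06). Of 21 BCL6 repression targets 7 rose and 1 fell, or 8 and 1 when adjusted over the list alone (mean 0.27, camera adjusted p = 0.00557). Among them were the cell cycle inhibitor CDKN1B (0.73 ± 0.08, adjusted p = 1.13e-05) and LITAF (0.64 ± 0.07, adjusted p = 3.06e-05). Of 21 integrated stress and unfolded protein response genes 9 rose and 0 fell, also 9 and 0 when adjusted over the list alone (mean 0.23, camera adjusted p = 0.000204). The serine synthesis enzyme PSAT1 rose by 0.51 ± 0.06 (adjusted p = 2.53e-05), MTHFD2 of mitochondrial folate metabolism by 0.35 ± 0.05 (adjusted p = 0.000204) and the stress transcription factor ATF4 by 0.28 ± 0.05 (adjusted p = 0.00205).

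MHC class II, B cell, germinal centre and interferon genes fell in Pfeiffer. Of 18 MHC class II presentation genes 9 fell and 0 rose, also 9 and 0 when adjusted over the list alone (mean -0.32, camera adjusted p = 1.29e-06). They included the cathepsins CTSS (-0.71 ± 0.06, adjusted p = 1.86e-06) and CTSH (-0.54 ± 0.05, adjusted p = 5.21e-06), which process antigen, and the peptide exchange chain HLA-DMA (-0.51 ± 0.05, adjusted p = 4.42e-06). Of 8 B cell markers 5 fell and 0 rose, also 5 and 0 when adjusted over the list alone (mean -0.45, camera adjusted p = 1.26e-05). The inhibitory receptor CD22 stood at -0.97 ± 0.12 (adjusted p = 7.56e-05) and MS4A1, which encodes CD20, at -0.39 ± 0.06 (adjusted p = 0.000371). Of 25 B cell receptor signalling genes 6 fell and 1 rose, or 7 and 1 when adjusted over the list alone (mean -0.16, camera adjusted p = 0.00557). They included the kinases SYK (-0.49 ± 0.05, adjusted p = 1.59e-05) and LYN (-0.38 ± 0.06, adjusted p = 0.000452). Of 25 germinal centre genes 8 fell and 2 rose, or 9 and 3 when adjusted over the list alone (mean -0.34, camera adjusted p = 0.00337). Besides SPIB they included the elongation factor ELL3 (-1.19 ± 0.07, adjusted p = 6.33e-08) and GCSAM (-0.65 ± 0.06, adjusted p = 6.65e-06). Of 25 interferon response genes 7 fell and 2 rose, also 7 and 2 when adjusted over the list alone (mean -0.33, camera adjusted p = 0.0023). The antiviral GTPase MX1 stood at -1.20 ± 0.14 (adjusted p = 4.05e-05), TRIM22 at -1.33 ± 0.17 (adjusted p = 9.55e-05) and the ubiquitin-like ISG15 at -0.70 ± 0.10 (adjusted p = 0.000173). The interferon call was lost with a stricter filter on dim genes (adjusted p = 0.336).

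Across the 9888 genes, 1603 passed in Pfeiffer, 781 higher and 822 lower, and 93 changed at least 2-fold. At an unadjusted p of 0.05, 2879 passed, and the arrays did not overlap for 33% of genes. Cholesterol synthesis was not called in Pfeiffer (mean 0.10, camera adjusted p = 0.342), where INSIG1 and STARD4 rose and LSS and SC5D fell, or 3 and 2 when adjusted over the list alone. Nor were the B cell activation and exit genes (mean 0.09, camera adjusted p = 0.673), with 3 higher and 2 lower, or 4 and 2 when adjusted over the list alone. Pfeiffer siRNA replicate 3 stood apart from the other Pfeiffer arrays in its 3' to 5' ratios and had the lowest array weight (0.413). Without it 1595 genes passed, BCL6 stood at -0.86 and all 11 called lists kept their call, with MHC class II presentation at -0.31 (camera adjusted p = 7.19e-06) and G2/M at 0.24 (camera adjusted p = 6.95e-10). Markers of T, NK, monocyte, stromal and epithelial cells, 37 genes in all, gave 0 limma calls in either line without a filter on dim genes. At an unadjusted p of 0.05, 2 were higher and 1 lower in OCI-Ly7, and 4 and 2 in Pfeiffer. GZMB, the cytotoxic granule protease granzyme B, is one of these markers and passed with the filter in both lines (adjusted p = 0.0361 in OCI-Ly7 and 0.0354 in Pfeiffer).

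Some genes changed in the same direction in both lines, though not always by the same amount. Among those named here, PRDM1 and BCL6 differed between the lines by 0.93 and -0.54 (limma, adjusted p = 0.00119 and 0.00496). TENT5C, a poly(A) polymerase of plasma cells, rose by 0.42 ± 0.07 in OCI-Ly7 and 1.15 ± 0.07 in Pfeiffer (adjusted p = 0.00524 and 5.13e-08), and the Ets factor ELK3 by 0.79 ± 0.11 and 0.81 ± 0.11 (adjusted p = 0.000908 and 9.62e-05). HSP90B1, PRDM1, PRSS2, CD69, SLC25A30 and GZMB were the other 6 of the 8 genes with the largest mean rise in both, averaging 0.91, 0.94, 1.09, 1.26, 1.18 and 0.99. MFSD1, a lysosomal transporter, fell by 0.70 ± 0.08 and 1.34 ± 0.08 (adjusted p = 0.000137 and 2.41e-08), and UBQLN2, a ubiquilin, by 0.68 ± 0.07 and 0.91 ± 0.07 (adjusted p = 0.000127 and 5.66e-07). KIF5C (-0.83 on average), LINC01857 (-0.76), PLEKHB2 (-0.71), SUDS3 (-0.70), MYBL1 (-0.69) and BCL6 (-0.69) completed the 8 largest falls.

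Among the 8 rises, CD69, GZMB, PRDM1 and SLC25A30 lost a call in a line without some array. These were all 6 OCI-Ly7 arrays and control replicate 1 and siRNA replicate 1 of Pfeiffer for CD69, all but OCI-Ly7 control replicate 2 for GZMB, the 3 arrays given above for PRDM1 and Pfeiffer control replicate 1 for SLC25A30 (adjusted p up to 0.115, 0.118, 0.0993 and 0.0512). With the mean of all probe sets, ELK3 (0.65, adjusted p = 0.0971), PLEKHB2 (-0.30, adjusted p = 0.498), KIF5C (-0.49, adjusted p = 0.326) and MYBL1 (-0.41, adjusted p = 0.386) were not called in OCI-Ly7, nor KIF5C (-0.62, adjusted p = 0.071) and MYBL1 (-0.30, adjusted p = 0.383) in Pfeiffer.

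The lines shared 36 genes that rose in both, where independent lists would share 13.2 (two-sided Fisher's exact p = 2.02e-08), and 35 that fell in both, where they would share 8.15 (exact p = 2.23e-14). Another 24 rose in OCI-Ly7 and fell in Pfeiffer (13.9 by chance, exact p = 0.00699), and 13 did the reverse (7.74 by chance, exact p = 0.0577). The contrasts of the 2 lines share 1 estimate of each gene's spread. A gene with a small estimate is thus more readily called in both lines, in the same or in opposite directions. The counts by chance take no account of this, and genes are not independent, so these p-values describe the overlap only. Over all 9888 genes the changes in the lines correlated with Pearson's r = 0.036 and Spearman's rho = 0.019, and over the 108 called in both with 0.443 and 0.452; the correlation is across genes, which are not independent replicates. Averaged over both lines 1045 genes passed, 560 higher and 485 lower. The 71 genes changed in the same direction became 30 without OCI-Ly7 siRNA replicate 1, 43 without siRNA replicate 3, 44 without control replicate 1, 45 without control replicate 3 and 47 without control replicate 2 of that line.

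**Figure D2:**
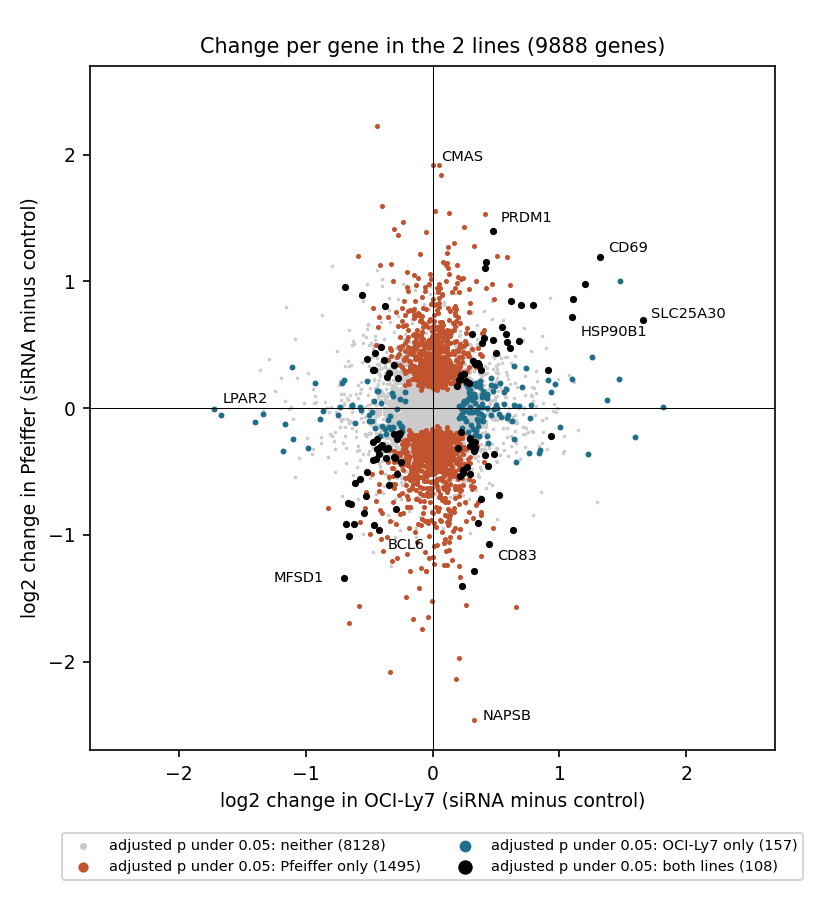
Change of each of the 9888 genes in OCI-Ly7 (horizontal) and Pfeiffer (vertical), as log2 of BCL6 siRNA minus control, with points coloured by the line in which the adjusted p was under 0.05. The 108 genes called in both lines lie along the diagonal for 71 genes and across it for 37, and 1495 were called in Pfeiffer alone.

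On average over both lines the lists of BCL6 repression targets (mean 0.24), plasma cell and secretory genes (0.19), G2/M genes (0.13), S phase genes (0.09), cholesterol synthesis (0.16) and stress response genes (0.12) were called higher, and germinal centre genes (-0.19) and B cell markers (-0.12) lower. Of the BCL6 repression targets 9 of 21 rose and 1 fell, or 11 and 1 when adjusted over the list alone, with LITAF at 0.59 ± 0.05 (adjusted p = 3.45e-06) and CDKN1B at 0.46 ± 0.05 (adjusted p = 7.1e-05). This list's call held with an estimated correlation (adjusted p = 0.0313). In the order above, the other 7 gave adjusted p = 0.114, 0.124, 0.222, 0.128, 0.0668, 0.0572 and 0.114 with an estimated correlation. The B cell markers were not called with the mean of all probe sets of a gene (adjusted p = 0.239). Only the BCL6 repression targets and the plasma cell and secretory genes were called higher in each line. Of the rest, cholesterol synthesis was called in OCI-Ly7 alone, the G2/M, S phase, stress and germinal centre lists in Pfeiffer alone, and the B cell markers in opposite directions. With an estimated correlation camera called the plasma cell list in neither line (adjusted p = 0.353 in OCI-Ly7 and 0.0918 in Pfeiffer). The S phase call in Pfeiffer was lost as well (adjusted p = 0.0893). The B cell activation and exit genes were not called on average (0.16, camera adjusted p = 0.0587) or for the difference (-0.14, camera adjusted p = 0.0542), nor was cholesterol synthesis for the difference (-0.11, camera adjusted p = 0.0511), but each of these passed when some arrays were left out (adjusted p down to 0.0156, 0.0145 and 0.00565).

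The lines differed in antigen presentation and B cell genes, which rose as lists in OCI-Ly7 and fell in Pfeiffer. The MHC class II genes differed by a mean of -0.50, Pfeiffer minus OCI-Ly7 (camera adjusted p = 8.82e-11), with 10 of 18 genes lower and 0 higher, or 13 and 0 when adjusted over the list alone. HLA-DMB differed by -1.43 ± 0.21 (adjusted p = 0.000535), CTSS by -0.80 ± 0.09 (adjusted p = 3.76e-05) and HLA-DMA by -0.76 ± 0.07 (adjusted p = 7.63e-06). The B cell markers differed by -0.65 (camera adjusted p = 1.37e-07; 6 of 8 lower and 0 higher, or 7 and 0 when adjusted over the list alone), with CD22 at -1.13 ± 0.18 (adjusted p = 0.000887). B cell receptor signalling differed by -0.24 (camera adjusted p = 0.000763; 8 of 25 lower and 2 higher, or 11 and 2 when adjusted over the list alone), with SYK at -0.73 ± 0.08 (adjusted p = 2.29e-05). The interferon response differed by -0.50 (camera adjusted p = 2.39e-05; 5 of 25 lower and 0 higher, or 8 and 0 when adjusted over the list alone), with MX1 at -1.35 ± 0.20 (adjusted p = 0.000668); its call was lost with a stricter filter on dim genes (adjusted p = 0.0643).

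**Figure D3:**
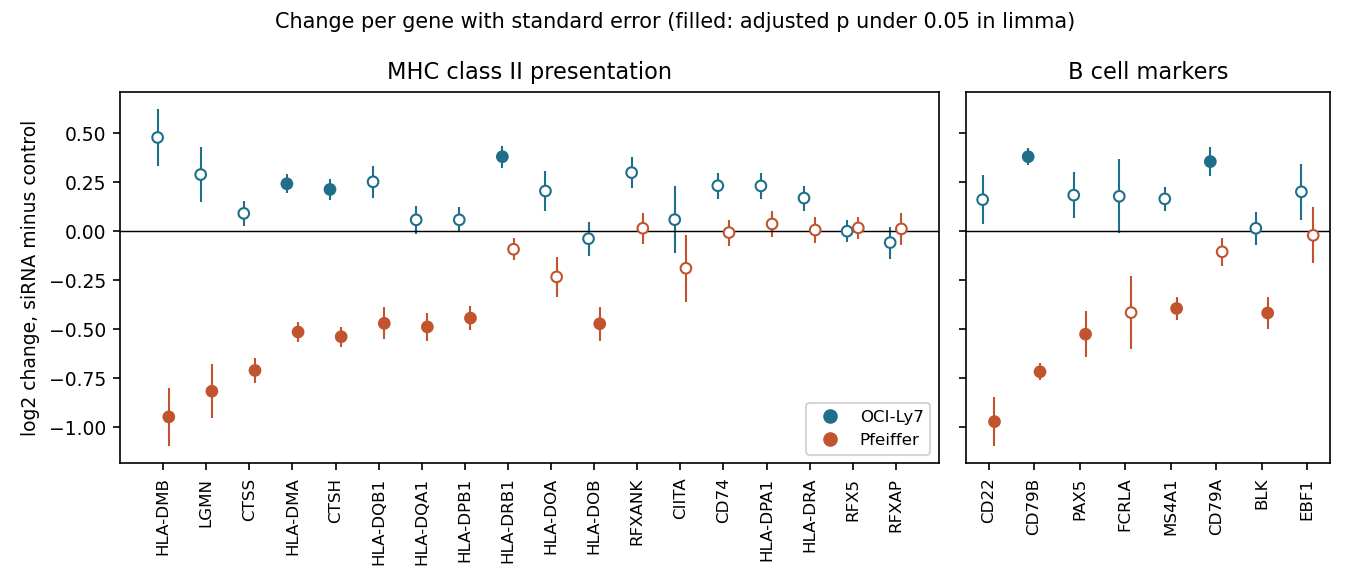
Change of each MHC class II presentation gene and B cell marker in OCI-Ly7 and Pfeiffer, as log2 of BCL6 siRNA minus control with its standard error, filled where limma's adjusted p was under 0.05. In Pfeiffer 9 of 18 and 5 of 8 genes fell, while in OCI-Ly7 3 and 2 rose and none of either list fell.

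The cell cycle lists were higher in Pfeiffer than in OCI-Ly7, by 0.27 for G2/M genes (camera adjusted p = 4.11e-10; adjusted p = 0.0735 with an estimated correlation) and 0.21 for S phase genes (camera adjusted p = 8.92e-07; adjusted p = 0.125 with an estimated correlation). Of the G2/M genes 8 of 29 were higher and 0 lower, or 14 and 0 when adjusted over the list alone, and of the S phase genes 6 of 28 and 0, or 7 and 0. MKI67 differed by 0.50 ± 0.09 (adjusted p = 0.0017) and RRM2 by 0.51 ± 0.07 (adjusted p = 0.000457). The stress response list differed by 0.20 (camera adjusted p = 0.00765; adjusted p = 0.0925 with an estimated correlation). Of its genes 6 of 21 were higher and 1 lower, also 6 and 1 when adjusted over the list alone, among them PSAT1 (0.57 ± 0.08, adjusted p = 0.000481). The germinal centre list differed by -0.30 (camera adjusted p = 0.0291; adjusted p = 0.0762 with an estimated correlation). Of its genes 6 of 25 were lower and 1 higher, or 8 and 2 when adjusted over the list alone, among them SPIB (-1.51 ± 0.13, adjusted p = 3.88e-06). With a stricter filter on dim genes neither the stress list (adjusted p = 0.178) nor the germinal centre list (adjusted p = 0.0643) was called. The germinal centre list was also not called without OCI-Ly7 control replicate 1 or Pfeiffer control replicate 3 (adjusted p = 0.0568 and 0.0511).

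Over all genes, the change differed between the lines for 870, 370 with the higher value in Pfeiffer and 500 with the lower. Beside NAPSB, AFF3, LINC01215 and ALOX5AP, the differences of which were -2.79, -2.33, -2.18 and -1.82, the largest negative ones were those of SATB1 (-2.23) and SHROOM1 (-1.83). The largest positive ones were those of LINC01943 (2.67), SOX2 (1.99), INHBE (1.95), CMAS (1.92), ZBED2 (1.92) and CSRP2 (1.87). The second CMAS probe set gave 0.01 in OCI-Ly7 and -0.06 in Pfeiffer. INHBE lost its call without OCI-Ly7 control replicate 2, Pfeiffer control replicate 3 or Pfeiffer siRNA replicate 2 (adjusted p up to 0.0643), SHROOM1 without Pfeiffer control replicate 3 (adjusted p = 0.0572), and ZBED2 without any array but OCI-Ly7 siRNA replicate 2 (adjusted p up to 0.109). The difference of LINC01943 was not called with a pseudocount of 1 (adjusted p = 0.174), nor that of SATB1 without a trend in eBayes (adjusted p = 0.0532). PRDM1 and IRF4 differed by 0.93 and 0.78 (adjusted p = 0.00119 and 0.00236). With the mean of their probe sets, dim ones included, they differed by 0.48 and 0.29 and were not called (adjusted p = 0.0715 and 0.492), although the second IRF4 probe set gave 0.07 in OCI-Ly7 and 0.71 in Pfeiffer.

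**Figure D4:**
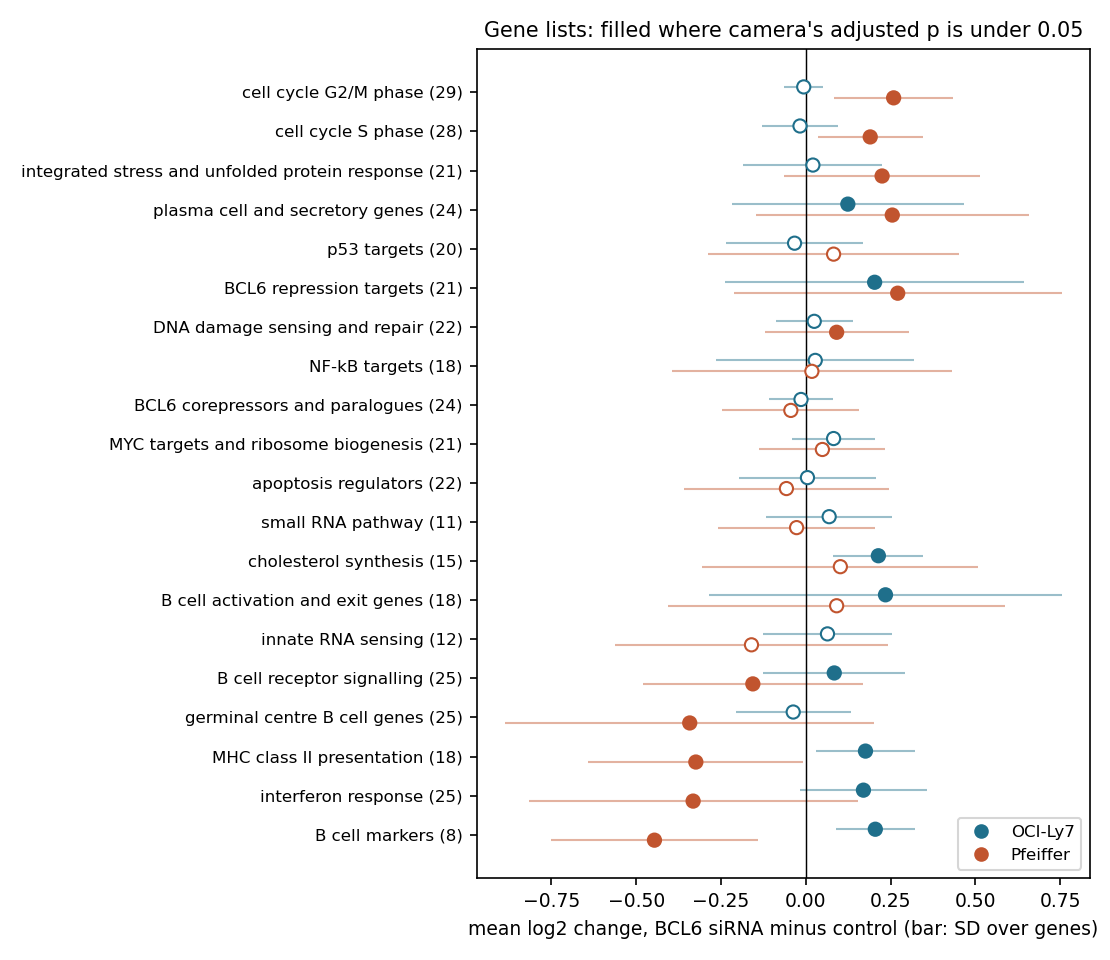
Mean change of each gene list, as log2 of BCL6 siRNA minus control, in OCI-Ly7 and Pfeiffer, with bars for the SD over the list's genes, the number of tested genes in brackets, and filled points where camera's adjusted p was under 0.05. The MHC class II, interferon, B cell marker and B cell receptor lists lie above 0 in OCI-Ly7 and below 0 in Pfeiffer.

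Several fixed lists were called by camera at the preset correlation in no comparison. Fry, which does not compare a list with other genes, called the apoptosis, p53 and innate RNA sensing lists in Pfeiffer (adjusted p = 0.00264, 0.00514 and 0.00281), the apoptosis and p53 lists on average (adjusted p = 0.0157 and 0.0331) and the apoptosis and innate RNA sensing lists for the difference (adjusted p = 0.0274 and 0.00726). The p53 targets stood at a mean of -0.03 in OCI-Ly7 and 0.08 in Pfeiffer over 20 genes (camera adjusted p = 0.604 and 0.375). There were 1 higher and 0 lower in OCI-Ly7 and 3 higher and 1 lower in Pfeiffer, or 1 and 0, and 4 and 1, when adjusted over the list alone. DDB2, a damage sensor, rose by 0.56 ± 0.08 in OCI-Ly7 (adjusted p = 0.00155) and the polymerase POLH by 0.79 ± 0.10 in Pfeiffer (adjusted p = 6.46e-05). The NF-kB targets stood at 0.03 and 0.02 over 18 genes (camera adjusted p = 0.346 and 0.677). There were 2 higher and 2 lower, and 5 higher and 3 lower, or 3 and 2, and 5 and 3, when adjusted over the list alone. CD83, one of them, rose by 0.45 in OCI-Ly7 and fell by 1.07 ± 0.06 in Pfeiffer, a difference of -1.51 ± 0.08 (adjusted p = 2.91e-08). The apoptosis regulators stood at 0.00 and -0.06 over 22 genes (camera adjusted p = 0.684 and 0.302). There were 1 higher and 2 lower, and 2 higher and 5 lower, or 1 and 2, and 3 and 5, when adjusted over the list alone. The survival gene BCL2A1 fell in Pfeiffer (-0.73 ± 0.09, adjusted p = 3.96e-05). In OCI-Ly7 the apoptosis list's mean was above 0 while its median (-0.002) and its test leaned down.

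The MYC targets and ribosome biogenesis genes stood at 0.08 in OCI-Ly7 and 0.05 in Pfeiffer (camera adjusted p = 0.328 and 0.253), with 0 of 21 called in OCI-Ly7 and 3 higher in Pfeiffer, or 0 and 2 when adjusted over the list alone. The BCL6 corepressors and paralogues stood at -0.01 and -0.04 (camera adjusted p = 0.604 and 0.46), with 0 of 24 called in OCI-Ly7 and 1 higher and 3 lower in Pfeiffer, the same counts when adjusted over the list alone. The deacetylase HDAC1 fell there by 0.57 ± 0.05 (adjusted p = 2.22e-06). The small RNA pathway stood at 0.07 and -0.03 (camera adjusted p = 0.514 and 0.817), with 0 of 11 called in OCI-Ly7 and 1 higher and 1 lower in Pfeiffer, or 2 and 1 when adjusted over the list alone. Innate RNA sensing stood at 0.06 and -0.16 (camera adjusted p = 0.604 and 0.0913), with 1 of 12 higher and 0 lower in OCI-Ly7 and 1 higher and 4 lower in Pfeiffer, the same counts when adjusted over the list alone. Without Pfeiffer siRNA replicate 3 camera called innate RNA sensing lower in Pfeiffer (-0.22, adjusted p = 0.0354), and for the difference it called it without that array, OCI-Ly7 control replicate 2 or Pfeiffer control replicate 2 (adjusted p = 0.0245, 0.0472 and 0.0391). It called the MYC targets higher on average without OCI-Ly7 control replicate 2, OCI-Ly7 siRNA replicate 3 or Pfeiffer siRNA replicate 2 (adjusted p = 0.0426, 0.0295 and 0.0231), and by line without the last 2 (adjusted p = 0.0294 in OCI-Ly7 and 0.0409 in Pfeiffer). Of other genes linked to BCL6, CDKN1A, MYC, CD44, CXCR4, ATR and CIITA were not called in either line, with values of -0.03, 0.05, -1.02, 0.20, 0.09 and 0.06 in OCI-Ly7 (adjusted p = 0.239 for CD44 and 0.738 for ATR) and -0.10, -0.16, 0.04, -0.10, -0.13 and -0.19 in Pfeiffer. The probe sets of BCL2, CCND2 and BCL6B were below the filter.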

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

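The tests of other-cell markers, of the spread between arrays and of a response scaled by the knockdown were chosen after the results were seen. The change differed between the lines for 870 genes by limma's test of the difference. BCL6 differed by -0.54, PRDM1 by 0.93, IRF4 by 0.78 and MKI67 by 0.50, Pfeiffer minus OCI-Ly7. With the mean of their probe sets, dim ones included, PRDM1 and IRF4 were not called. The most positive differences were those of LINC01943 (2.67), SOX2 (1.99), INHBE (1.95), CMAS (1.92), ZBED2 (1.92) and CSRP2 (1.87), and the most negative those of NAPSB (-2.79), AFF3 (-2.33), SATB1 (-2.23), LINC01215 (-2.18), SHROOM1 (-1.83) and ALOX5AP (-1.82). Of these calls, that of SHROOM1 ended without Pfeiffer control replicate 3 (adjusted p = 0.0572). That of INHBE ended without OCI-Ly7 control replicate 2, Pfeiffer control replicate 3 or Pfeiffer siRNA replicate 2 (adjusted p up to 0.0643). ZBED2 lost its call without any array but OCI-Ly7 siRNA replicate 2 (adjusted p up to 0.109). A pseudocount of 1 ended the call of LINC01943, and eBayes without a trend that of SATB1. The second CMAS probe set gave 0.01 in OCI-Ly7 and -0.06 in Pfeiffer. The lists whose mean differed were B cell markers (-0.65), interferon response (-0.50), MHC class II presentation (-0.50), germinal centre genes (-0.30), B cell receptor signalling (-0.24), G2/M (0.27) and S phase (0.21) genes and the stress response (0.20). With an estimated correlation the germinal centre, G2/M, S phase and stress lists lost that call (adjusted p = 0.0762, 0.0735, 0.125 and 0.0925). The germinal centre call ended without OCI-Ly7 control replicate 1 or Pfeiffer control replicate 3 (adjusted p = 0.0568 and 0.0511). A stricter filter on dim genes ended the interferon, stress and germinal centre calls. Among 4796 probe sets without a single gene, 31 changed in OCI-Ly7 and 322 in Pfeiffer, signals that no comparison of genes used.

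The mean of the MHC class II list was 0.18 in OCI-Ly7 and -0.32 in Pfeiffer, a difference of -0.50, though only CTSH and HLA-DMA were called in both lines, in opposite directions, and in OCI-Ly7 these calls ended without 9 and 4 of the arrays (adjusted p up to 0.144 and 0.0692), without a trend in eBayes (adjusted p = 0.122 and 0.0683) and with a replicate block (adjusted p = 0.109 and 0.0622). The scaling of the arrays is argued against, since quantile normalization left -0.51 (camera adjusted p = 2.36e-13). A trend with signal level is argued against too: the 2.5th percentile of 10000 random lists matched on level was -0.14 and the lowest was -0.28. RNA of other cells stays open: without a filter limma called 0 of 37 markers higher in Pfeiffer (mean 0.06; 4 at an unadjusted p of 0.05), but only 7 pass the filter on dim genes, a bound set after the values were seen, and GZMB passed with it in both lines (adjusted p = 0.0354 in Pfeiffer). That GZMB call in Pfeiffer was itself lost without any of 6 arrays. A response that depends on the line remains as a hypothesis, as do the different controls that the Pfeiffer titles hint at.

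Fewer genes were called in OCI-Ly7 than in Pfeiffer, 265 against 1603; the OCI-Ly7 count was 101, 135, 149 and 159 without its siRNA replicate 1, siRNA replicate 3, control replicate 3 and control replicate 1. For a larger spread between its arrays, the median residual SD was 0.111 in OCI-Ly7, not above the 0.123 in Pfeiffer. Both counts, however, rest on 1 shared estimate of each gene's spread, with a median SE of 0.107 in each line. A larger spread in OCI-Ly7 alone would not have raised its SE over that of Pfeiffer, so this comparison does not bear on the counts. One response scaled by the depth of the knockdown would need OCI-Ly7 changes near 0.439 of those in Pfeiffer, the ratio of the BCL6 changes, over the 1602 other genes called in Pfeiffer, or 0.377 and 0.17 by the other BCL6 probe sets. The slope was 0.043, at most 0.050 on leaving out an array, and 52.9% of these genes had the same sign in both lines. A steeper dependence on BCL6 level, and different programmes in the lines, may both remain, and these data do not separate them. Effects of the siRNA on transcripts other than BCL6 were not tested. Opposite directions argue against a steeper dependence alone for the MHC class II list (0.176 in OCI-Ly7, -0.324 in Pfeiffer). The same holds for the B cell markers (0.205 and -0.446). The different control that the Pfeiffer titles hint at stays open as well. It could add changes in Pfeiffer alone, which would raise the count there and lower the slope.

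Other splits of the arrays bear on the counts. For the 2 lines alone, 10 splits of 3 against 3 are too few for a share under 0.05: 1 split, the real one, gave 265 genes in OCI-Ly7 (highest other 5) and 1603 in Pfeiffer (highest other 2), and 8 and 11 lists (highest others 6 and 5). Leaving out 1 of OCI-Ly7 siRNA replicates 1 and 3 and control replicates 1 and 3 gave 101 to 159 genes in that line. Over 100 of the 200 splits within both lines, only the real one reached the 1045 genes changed on average (highest other 586). The same held for the 71 changed in both lines in the same direction (highest other 1) and the 870 that differed (highest other 559). The 71 became 30 to 47 without OCI-Ly7 siRNA replicate 1 or 3 or any of its controls. A swap of siRNA and control in 1 line was not among the splits drawn. It would exchange the counts for average and difference, so that 1045 would exceed the 870, and would give 37 in the same direction. These counts argue against chance for the splits drawn only, and the arrays may be technical replicates. Chance cannot be excluded for the number of lists called. At least the 8 lists of the average came from 10 splits (highest other 12), and at least the 8 of the difference from 9 (highest other 11).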

How the results depend on the processing

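The filter within the tested line and the other BCL6 probe sets were tried after the data were seen, and all other alternatives were planned. Of the alternatives' results for named genes that were called, 6555 kept direction and call, 520 lost the call and 7 reversed. For called lists 885 kept both and 44 lost the call. The list tests under array weights and without a trend in eBayes only repeated the main list test. The 35 called lists kept under each of these settings were thus fixed in advance and show nothing. The named genes were mostly picked for large changes or low p, so this tally does not describe all called genes. The cause was not tested unless given. BCL6 in OCI-Ly7 was not called with the third BCL6 probe set (-0.17, adjusted p = 0.429). Without a filter on dim genes more genes were tested, and OCI-Ly7 had 164 genes, both lines 44 and the average 13 lists. Averaging the probe sets of a gene gave 133 genes in OCI-Ly7, 1027 in Pfeiffer, 611 on average, 534 for the difference and 34 in both, and testing every probe set, 2556 in Pfeiffer and 1321 for the difference. Without a trend OCI-Ly7 had 142 and both lines 38. A 2-fold minimum, which removes smaller changes by construction, left 22, 93, 9, 108 and 1. Keeping the upper 0.25 of genes gave 5 lists for the difference, camera with an estimated correlation 5, 1 and 4 lists for OCI-Ly7, the average and the difference, and fry 15 for the average. Reversed were LILRA2 in Pfeiffer (-1.53) with a pseudocount of 1, where another probe set was brightest, IKBKE on average (0.026) with 64, CD79B on average (0.023), XBP1 in OCI-Ly7 (-0.059) and HDAC5 in Pfeiffer (0.15) with the mean of probe sets, and IDI1 on average (-0.10) and WNT7B in OCI-Ly7 (-0.21) without probe sets that can bind related transcripts. Quantile normalization moved the share of calls that were higher in OCI-Ly7 from 63% to 59.9%. A filter within the line gave 237, 1527, 1033 and 904 genes and 74 in both.

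The replicate numbers did not pair the arrays: same-numbered siRNA and control arrays deviated with r from -0.08 to 0.083, and 2 of 6 siRNA arrays matched their own number best. With a replicate block, OCI-Ly7 had 139 genes, both lines 43, Pfeiffer 1390, the average 817 and the difference 684. The block also ended 1 call of a list and 34 calls of named genes.

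Leaving out 1 array each gave BCL6 changes of -0.45 to -0.40 in OCI-Ly7 and -1.03 to -0.86 in Pfeiffer, and 101 to 337 genes in OCI-Ly7, 1118 to 1611 in Pfeiffer, 783 to 1132 on average, 648 to 992 for the difference and 30 to 83 in both. Lists called ran from 6 to 8, 10 to 12, 8 to 11 and 7 to 12. The lowest counts for OCI-Ly7 and for both came without OCI-Ly7 siRNA replicate 1. Fewer arrays lower the power by construction. Array weights were lowest for Pfeiffer siRNA replicate 3 (0.413). Signal over background limits genes that are dim in the tested line.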

Other observations

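The lists of this part were written after the main results were seen. Their predictions were written before their own tests, but the rules for reading the outcomes were settled after the values were seen. At first a claim was to hold with an estimated correlation as well, and by that first rule both the transfer RNA claim and the claim on the endoplasmic reticulum below stay open. A list of genes for charging transfer RNA and for making or carrying amino acids was called higher in Pfeiffer: of 20 such genes outside the fixed lists, 11 rose and 1 fell (mean 0.23, camera adjusted p = 2.22e-06; adjusted p = 0.0667 with an estimated correlation). WARS1, SARS1, TARS1 and YARS1, which charge transfer RNAs, and SHMT2, which makes glycine, were among those that rose, as were the transporter genes SLC3A2 and SLC7A1. The gene that fell, ALDH18A1, serves proline synthesis, and no gene of that pathway rose. In OCI-Ly7 0 of 20 passed in limma, with 2 higher and 1 lower at an unadjusted p of 0.05 (mean 0.02, camera adjusted p = 0.544), and the difference between the lines was 0.21 (camera adjusted p = 6.15e-05; adjusted p = 0.123 with an estimated correlation). A broader amino acid response in Pfeiffer is the hypothesis. The test met the written prediction at the preset correlation only.

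Genes of folding in and export from the endoplasmic reticulum were tested as a response of both lines. Their mean over 34 genes was 0.071 on average (camera adjusted p = 0.00143; adjusted p = 0.125 with an estimated correlation), which met the written prediction. By line the mean was 0.13 in OCI-Ly7 (camera adjusted p = 2.09e-06; adjusted p = 0.0535 with an estimated correlation), where SEC61A1 and MANF were among 5 genes that rose, and 0.02 in Pfeiffer (camera adjusted p = 0.413), where 6 rose and 1 fell. A rise in both lines is thus open. Lysosomal genes were tested as fellows of the MHC class II genes and cathepsins that fell in Pfeiffer. Their mean there was -0.037 over 33 genes (camera adjusted p = 0.413; adjusted p = 0.637 with an estimated correlation), with 4 higher and 5 lower, so the prediction for Pfeiffer was not met. In OCI-Ly7 the mean was 0.08 (camera adjusted p = 0.036; adjusted p = 0.228 with an estimated correlation), with LAMP1 higher and LAMP2 lower, and the difference was -0.12 (camera adjusted p = 0.0481; adjusted p = 0.221 with an estimated correlation).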
